A study of Caenorhabditis elegans with 3 samples.

How the data were processed

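The data are peak lists from ChIP-seq of RPC-1 fused to GFP and a FLAG tag, pulled down with an antibody against GFP, in whole young adult *C. elegans* hermaphrodites. Per the labels, there were 3 biological replicates of 1 group, and chromatin was fragmented by sonication. The deposited file lists name a control alignment behind each peak list, and the control was not analysed here. The aligner, the peak caller, its settings and the read length are not given in the sources used here.

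The deposit holds, for each of the genome builds ce10 and ce11, a list for each replicate, a list for the replicates pooled, and a list of reproducible peaks kept by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks hold between replicates. The deposited lists give each peak's signal, which is the peak caller's own value set within a list, and it was used only to rank and describe peaks within that list. They also give a −log10 q value deposited by the authors, which was at 1 value throughout each reproducible list and was not used for ranking. Start, end and summit were taken as deposited and are given here counted from 1. The replicate and pooled lists were made as input for IDR and hold weak peaks and background too, per the deposited file lists, so they were used by rank only. Read numbers are not part of these lists, so no depth per sample can be given, and intervals on shares cover the counting of genes or peaks only. The deposited file list names the pooled and the replicate lists as the sources of the reproducible list on each build. On ce11 none of the 1914 reproducible peaks was found in those lists with the same interval and summit, and on ce10 all 2283 were found in the pooled list. Which call the reproducible ce11 list came from is not known, and class occupancy, the share of peaks at Pol III genes, the comparisons between kinds of tRNA genes and the promoter lists were repeated with the strongest 1914 peaks of the pooled ce11 list.

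The reference was the assembly WBcel235, which is the same sequence as ce11, with its RefSeq annotation. No ce11 peak ran past the end of a chromosome. Coordinates on ce10 were not converted or annotated. Mitochondrial genes and peaks were left out of the ce11 comparisons. Gene classes were taken from the annotated type, product or symbol. The U6 genes were the 22 small nuclear RNA genes holding the sequence ACAGAGAAGATTA. Stem-bulge RNA genes, planned as a Pol III class, were not found by name in the annotation and were not analysed as a class. Any annotated under other names would be counted in another class, such as the other non-coding RNA genes.

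A gene was called occupied where a peak overlapped it by at least 1 bp, and a protein-coding gene where a peak overlapped 250 bp either side of a TSS. The random expectation came from 10000 placements of the merged peak regions at random positions on their own chromosome (1000 placements for the alternatives). Class p-values are one-sided for more overlap than random and were adjusted by the method of Benjamini and Hochberg over 15 classes, and are called permutation p-values because the peak positions were permuted. This test treats all positions of a chromosome alike, and genes in clusters share peaks, so circular shifts that keep the spacing of the peaks (1000 shifts) were tried too. Peaks were assigned by summit in this order: a Pol III gene within 200 bp, another small RNA gene or tRNA pseudogene within 200 bp, a protein-coding TSS within 500 bp, a protein-coding gene body, and between genes. Shares have exact (Clopper-Pearson) 95% intervals. Shares of peaks count each of the 1914 summits, although the list has 1673 distinct intervals, so summits on a shared interval are not independent and the intervals on these shares are too narrow to that extent. Occupancy was compared between kinds of tRNA genes by two-sided Fisher exact tests and between isotypes by 100000 permutations. The B box was searched as GGTTCRANYCC with at most 1 mismatch, on the sense strand of genes and on either strand around the summits of peaks away from genes. Replicate values are the mean and SD of 3 lists, each limited to the strongest 1914 peaks where so stated, and no test between replicates was made. Promoter lists were tested by one-sided Fisher exact tests against all other protein-coding genes, with adjustment over 14 lists. The gene lists, the gene classes other than tRNA pseudogenes, the tests of the main comparisons and most alternatives were chosen before the data were examined. The class of tRNA pseudogenes, the snoRNA and U6 summit positions and the tests named as such with the additional observations were chosen later.

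Genes were named by a rule fixed at the same time. It took all members of Pol III classes with up to 5 genes, and of larger classes the 5 occupied genes with the highest reproducible signal and up to 5 genes without a peak in genome order. Of the tRNA genes it took the 10 with the highest signal among those overlapped in all replicates. Of the protein-coding genes it took the 10 with the highest signal at a TSS and away from Pol III genes, rpc-1, and up to 4 members of each promoter list with a peak. Isotypes with an adjusted p under 0.05 were to be named, and there were 0. Histidine, glycine, phenylalanine, proline, serine and threonine tRNA genes were named after their values were seen. Of the 21U-RNA genes and the other non-coding RNA genes the counts are given without names, because most of those with a peak share it with a Pol III gene.

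The alternatives were the strongest 957 reproducible peaks, the strongest 1914 peaks of the pooled list, the 1608 reproducible peaks overlapped by a top peak of every replicate, the same without each replicate in turn, peaks shortened to 100 bp either side of the summit, and circular shifts. The settings without a replicate only drop the demand for overlap with that replicate's top peaks. The reproducible list itself, made from all 3 replicates per the deposited file list, was not called again. Asking for a summit within 100 bp of the gene gives the same occupancy as shortened peaks by construction, and both are given as 1 setting. Shortening does not move summits, so it does not enter the assignment of peaks or the promoter lists, which were repeated with distances of 100 bp and 250 bp. Chosen after the data had been seen were 4 further alternatives: promoter lists without peaks near snoRNA genes or tRNA pseudogenes, tRNA occupancy from each replicate's own top peaks, snoRNA genes with 100 bp upstream added, and 5S genes with less than 50% repeated sequence. Replicate results were repeated without each replicate and with other numbers of top peaks. Repeated sequence was measured as the share of 36-base words, on both strands, found more than once in the genome, over a gene and 200 bp either side. Matches to tRNA genes were searched with BLAST 2.17.0 (blastn task, E under 1e-05) in 150 bp either side of a summit. The code was tested on simulated peaks: 100% of 200 tRNA genes given a peak were recovered, overlap calls equalled those of a direct search at 100% of 612 tRNA genes, and 9 of 100 randomly placed lists gave a tRNA class p at or under 0.05. Python 3.11.15 was used with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.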

Results

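Binding of RPC-1 along the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the nematode *Caenorhabditis elegans*. RPC-1 is the largest subunit of RNA polymerase III (Pol III), the enzyme that transcribes tRNA genes, 5S rRNA genes and other short RNA genes. The animals carried RPC-1 fused to green fluorescent protein, and the fusion protein was pulled down with an antibody against that tag from whole young adult hermaphrodites. All samples formed 1 group of 3 biological replicates, so the comparisons below were made between gene classes and not between conditions. The peak lists of replicates 1, 2 and 3 on genome build ce11 held 24182, 24563 and 30000 peaks, and a list called on the pooled replicates held 30000. The reproducible ce11 list of the authors held 1914 peaks with separate summits on 1673 distinct intervals, which merged into 1521 regions and covered 1064811 bp, or 1.06% of the nuclear genome. Read numbers are not given in these lists, so the sequencing depth behind a peak is unknown. None of the 1914 reproducible ce11 peaks had the same interval and summit as a peak of the pooled list or of a replicate list, whereas 2283 of 2283 reproducible peaks of build ce10 matched the pooled ce10 list. Values from the replicate lists are therefore given beside several of the values from the reproducible ce11 list.

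The first comparison asked which share of the tRNA genes carried RPC-1. A reproducible peak overlapped 590 of the 612 nuclear tRNA genes, or 96.4% (exact binomial 95% interval 94.6 to 97.7%). Random placements of the same regions on their own chromosomes overlapped 8.91 tRNA genes on average and at most 26. In the replicates' own lists, the strongest 1914 peaks overlapped 95.4% ± 0.283 of the tRNA genes (mean ± SD, n = 3). Of the 10 tRNA genes with the highest signal among those covered in all replicates, 9 lay on the X chromosome. A peak with signal 8035 spanned M02F4.t2, a glutamate tRNA gene (X, 3035976 to 3036047), and M02F4.t1, a glycine tRNA gene (X, 3036164 to 3036235), both outside protein-coding genes. The valine tRNA gene R04D3.t2 (X, 13307034 to 13307106) had signal 7493, and the lysine tRNA gene E03E2.t3 (X, 5713652 to 5713724) had 7467. The alanine tRNA gene T07H6.t1 (X, 6286321 to 6286392), which lies inside lev-9, had signal 7211. The threonine tRNA genes T25B6.t2 (X, 9024413 to 9024484) and F38G1.t1 (X, 487815 to 487886) had signals of 7177 and 6603. A pair of alanine tRNA genes inside him-4, F15G9.t1 and F15G9.t2, shared a peak with signal 7162. The lysine tRNA gene ZK994.t2 (V, 8499564 to 8499636), inside pxn-1, was overlapped by a peak with signal 9368 whose summit lay 934 bp away, next to the snoRNA gene ZK994.7. The 22 tRNA genes without a peak included 3 glycine tRNA genes inside pash-1 on chromosome I (T22A3.t4, T22A3.t2 and T22A3.t3), the phenylalanine tRNA gene Y95D11A.t1 (I, 10945821 to 10945893) and the lysine tRNA gene F37A4.t1 (III, 6724135 to 6724220). The test was a one-sided permutation of the peak positions by 10000 random placements (p = 0.0001, the smallest they can give, and Benjamini-Hochberg adjusted p = 0.000214 over 15 gene classes). Peak signal is the authors' own value and ranks peaks within a list only.

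The same measurement was made for the other gene classes transcribed by Pol III. All 5 genes of the signal recognition particle RNA were overlapped, as were rpr-1 (the RNA of RNase P), mrpr-1 (the RNA of RNase MRP) and yrn-1 (the Y RNA). Of the 22 U6 spliceosomal RNA genes, 17 were overlapped (77.3%, interval 54.6 to 92.2%). Of the 16 annotated 5S rRNA genes, 3 were overlapped (18.8%, interval 4.05 to 45.6%). The strongest 1914 peaks of a replicate overlapped 16 ± 1 U6 genes and 3 ± 0 5S genes (mean ± SD, n = 3). The signal at rpr-1 (I, 13463955 to 13464207) was 3487, at mrpr-1 (II, 7200233 to 7200418) 3121 and at yrn-1 (IV, 7499508 to 7499612) 2971. The strongest U6 gene was W05B2.8 (III, 10989679 to 10989780, inside dhc-4) with signal 6175, followed by F54D8.7 with 3819. The U6 genes without a peak were B0205.15, T20D3.12, T20D3.13, K09B11.15 and F32D1.12, and no replicate list held a peak over any of these 5. The signal recognition particle RNA genes were weaker than W05B2.8, F54D8.7, rpr-1, mrpr-1 and yrn-1. They ran from 1145 at srpr-2.1 through 980 at srpr-1.2, 738 at srpr-1.1 and 731 at srpr-2.2 to 96.6 at srpr-3 (V, 9293334 to 9293632). Their median of 738 was near the median of 832 of all occupied U6 genes. The occupied 5S genes were rrn-4.15 (V, 17428879 to 17428996) with signal 2771, rrn-4.2 with 273.3 and rrn-4.4 with 237, while rrn-4.16, rrn-4.3, rrn-4.5, rrn-4.1 and rrn-4.6 were among the 13 without a peak. The adjusted permutation p was 0.000214 for U6 and signal recognition particle RNA genes, 0.00200 for 5S rRNA genes, 0.0130 for yrn-1 and 0.0134 for rpr-1 and for mrpr-1. With only the strongest 957 peaks, 6.25% of the 5S genes were overlapped and the class no longer passed (adjusted permutation p = 0.140, against 0.00167 to 0.0138 under the other alternatives planned).

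**Figure D1:**
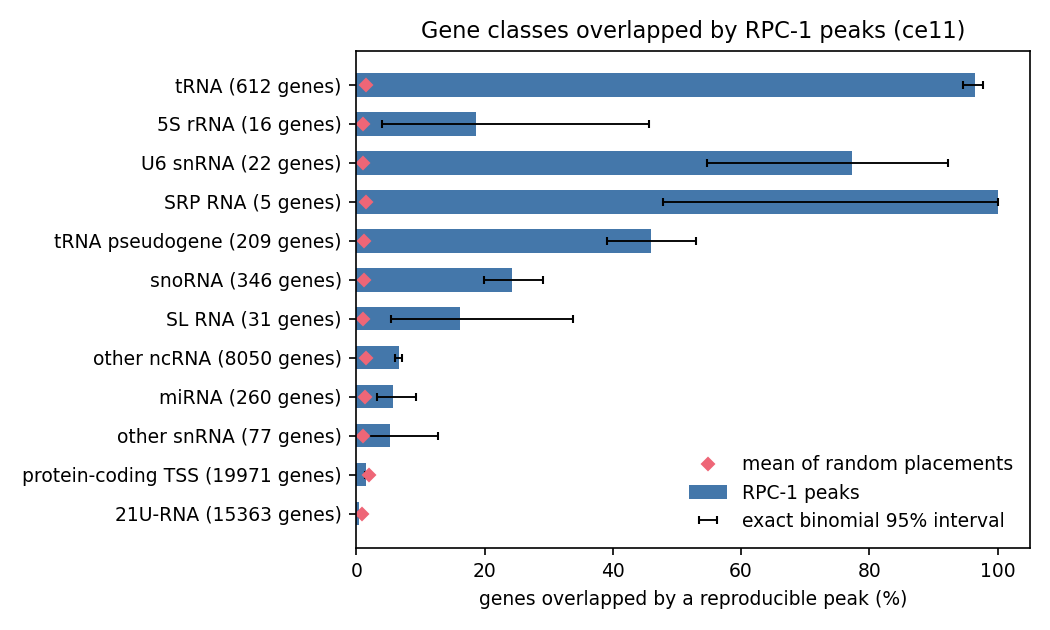
Share of the genes of each class overlapped by a reproducible RPC-1 peak on ce11 (bars, percent, with exact binomial 95% intervals) and the mean of 10000 random placements (diamonds); the classes with 1 gene each are left out. The tRNA genes stood at 96.4% and the snoRNA genes at 24.3%, against 1.46% and 1.16% in random placements.

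Classes of small RNA genes not counted as Pol III genes were measured in the same way for comparison. They are not a negative control. SnoRNA genes can hold Pol III promoters, and some spliced leader RNA genes sit in the 5S rRNA gene repeat. Peaks overlapped 84 of 346 small nucleolar RNA (snoRNA) genes, which guide modification of other RNAs (24.3%, interval 19.9 to 29.1%, adjusted permutation p = 0.000214), and the strongest peaks of the list were among them. The snoRNA genes C51F7.4 (V, 12303599 to 12303693) and C51F7.3 (V, 12303708 to 12303783), both inside frm-7, shared the strongest peak of all, with signal 9672, and that peak also ranked first in the list of each replicate. T19B4.8 (I, 5707046 to 5707119) had signal 7938 and T04A8.17 (III, 4689634 to 4689771, inside ppat-1) had 7863. The strongest 1914 peaks of a replicate overlapped 90.7 ± 3.06 snoRNA genes and 80.7 ± 2.08 tRNA pseudogenes (mean ± SD, n = 3). Of the 84 occupied snoRNA genes, 80 were overlapped by one of the strongest 1914 peaks of every replicate, and 3 shared their peak with a Pol III gene. The snoRNA genes Y74C9A.6, F53G12.12, T13E5.1, Y65B4BR.12 and Y65B4A.10 on chromosome I had none. Peaks overlapped 96 of 209 tRNA pseudogenes (45.9%, adjusted permutation p = 0.000214), with a median signal of 309 against 3312 at occupied tRNA genes, and the strongest 957 peaks overlapped 19.1% of the pseudogenes. The class of other non-coding RNA genes had 534 of 8050 overlapped (6.63%, adjusted permutation p = 0.000214), but at 402 of these the peak also covered a Pol III gene. The other 132 genes made up 1.64% of the class and were not tested on their own. Random placements of all regions overlapped 1.51% of the class. Those placements include the regions that cover Pol III genes, so 1.51% is not the expectation for the 132 genes. Among the microRNA genes 15 of 260 were overlapped (5.77%, adjusted permutation p = 0.000750), with the highest signals at mir-51 (6696), mir-4936 (5488) and mir-4812 (4439), and a peak of signal 4286 over mir-2212 and mir-1819 also covered 4 tRNA genes. The spliced leader RNA genes had 5 of 31 overlapped (16.1%, adjusted permutation p = 0.000214), led by sls-2.9 (I, 13297877 to 13297985) with signal 3965, whose peak also covered the tRNA gene M01E5.t1, and then sls-2.1 with 163. Of the other spliceosomal RNA genes 4 of 77 were overlapped (5.19%, adjusted permutation p = 0.0158), namely M163.13, F38E11.10, sup-6 and C52E4.8. The 21U-RNA genes, which encode piRNAs, were overlapped at 76 of 15363 genes (0.495%) against 0.865% in random placements, and protein-coding transcription start sites (TSS) at 313 of 19971 genes (1.57%) against 2.03%, and neither passed the test for enrichment (adjusted permutation p = 1). The lower tail of the same placements, which was not the planned test and was not adjusted, gave a permutation p of 0.0024 for 21U-RNA genes and 0.0001, the smallest they can give, for TSS. Both classes were nearer to random placements in the strongest 1914 peaks of the pooled list. The 21U-RNA genes were at 0.690% there, against 0.881%, and TSS at 1.91%, against 2.02%. The lower tail was not taken for that list. In the reproducible peaks found in every replicate, the spliced leader class fell to 6.45% (adjusted permutation p = 0.0512) and the other spliceosomal class to 2.60% (adjusted permutation p = 0.202). Neither passed there, without replicate 1 (0.0549 and 0.211 by the same permutation test), without replicate 3 (0.0549 and 0.182) or with the strongest 957 peaks (0.225 and 0.462), whereas both passed without replicate 2 (0.0375 and 0.0484). Both also passed with the strongest 1914 peaks of the pooled list (16.1% and 9.09%, adjusted permutation p = 0.00167 for each). With shortened peaks both passed as well (adjusted permutation p = 0.00167 and 0.00624).

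The next comparisons asked whether the setting of a tRNA gene went with its occupancy. On the X chromosome, which holds 276 of the tRNA genes, 267 were overlapped (96.7%), against 323 of 336 on the autosomes (96.1%), a difference of 0.608 percentage points (two-sided Fisher exact p = 0.828). Of the tRNA genes inside a protein-coding gene 280 of 291 were overlapped (96.2%), against 310 of 321 outside (96.6%, two-sided Fisher exact p = 0.831). A B box, the internal site bound by the initiation factor TFIIIC, was found with at most 1 mismatch in 511 of 590 occupied genes (86.6%) and in 18 of 22 genes without a peak (81.8%, two-sided Fisher exact p = 0.523). Isotypes as a whole passed a test for a difference in occupancy (permutation p = 0.0463, 100000 permutations of the isotype labels over the 612 genes). None of the 22 groups (1 of them 5 genes with no isotype given) passed alone after adjustment. The permutations treat each gene as independent, but some genes without a peak lay together, such as the glycine tRNA genes T22A3.t4, T22A3.t2 and T22A3.t3. These held 57.8%, 56.9% and 77.7% repeated 36-base words. The p-value may therefore be too small, and it cannot separate isotype from shared loci. The histidine tRNA genes came nearest, with 16 of 20 overlapped (80%, against 96.96% of the other tRNA genes, Fisher exact p = 0.00417, adjusted p = 0.0917), and this was the only isotype with an unadjusted p under 0.05. The glycine tRNA genes had 51 of 55 overlapped and the phenylalanine tRNA genes 12 of 14, both with adjusted p = 0.738 by Fisher's exact test, and the proline, serine and threonine tRNA genes were all overlapped (42, 39 and 34 genes). With only the strongest 957 peaks the X chromosome exceeded the autosomes by 4.28 percentage points (Fisher exact p = 0.0359), and with peaks shortened to 100 bp either side of the summit it was below them by a difference of -3.13 points (Fisher exact p = 0.205). The nested and B box differences also changed sign under at least 1 alternative, without passing the Fisher exact test under any.

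Peaks were then assigned by their summit to a kind of gene, in a fixed order with Pol III genes first and not by the nearest gene. Of the 1914 peaks 612 had a summit within 200 bp of a Pol III gene (32.0%, exact binomial 95% interval 29.9 to 34.1%), against 0.348% of randomly placed summits (p = 0.0001, the smallest that 10000 placements can give). The tRNA genes took 573 of these peaks, with a median signal of 2936. Another 79 peaks lay at snoRNA genes, with a median signal of 3507, and 90 at tRNA pseudogenes, with a median of 257. No annotated small RNA gene lay within 200 bp of 1018 summits (53.2% of the peaks), whose median signal was 238; 146 of these were within 500 bp of a protein-coding TSS, 395 in the body of a protein-coding gene and 477 between genes. When the list was divided into 4 parts of near-equal size by signal, in the strongest part 377 peaks (78.9%) were at Pol III genes and 33 (6.90%) away from every annotated small RNA gene, and in the weakest part 28 (5.85%) and 373 (77.9%) were. With only the strongest 957 peaks the share at Pol III genes was 57.2%.

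Within the replicates' own lists the tRNA genes took the upper ranks. Of the strongest 1914 peaks of a replicate, 35.96% ± 1.14 overlapped a tRNA gene (mean ± SD, n = 3), and of the strongest 250 the share was 70.5% ± 1.01. The snoRNA genes took 17.3% ± 0.462 of the strongest 250 peaks and 5.50% ± 0.218 of the strongest 1914. Peaks over tRNA genes had a median percentile rank of 98.2 ± 0.267 in a replicate's list, where the strongest peak stands at the top, and peaks over U6 genes one of 96.7 ± 0.172. Peaks over tRNA pseudogenes ranked at 93.3 ± 0.924, over snoRNA genes at 92.0 ± 0.0787 and over protein-coding TSS at 58.1 ± 0.936. In the upper 50% of each list the order of the pseudogenes (87.1 ± 1.70) and snoRNA genes (88.1 ± 1.24) was the opposite. The rank of tRNA peaks exceeded that of TSS peaks by 40.0 ± 0.826 percentile points, in 3 of 3 replicates. Chromosomes were compared per gene, by the strongest peak over each tRNA gene, and not per peak as above. Among tRNA genes with a peak, the median percentile rank was 99.2 ± 0.0984 on the X chromosome and 98.4 ± 0.164 on autosomes. The difference was 0.827 ± 0.117 percentile points, with the same sign in 3 of 3 replicates. With 3 replicates an exact sign-flip test cannot give a p below 0.25, so no test was made of these differences.

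**Figure D2:**
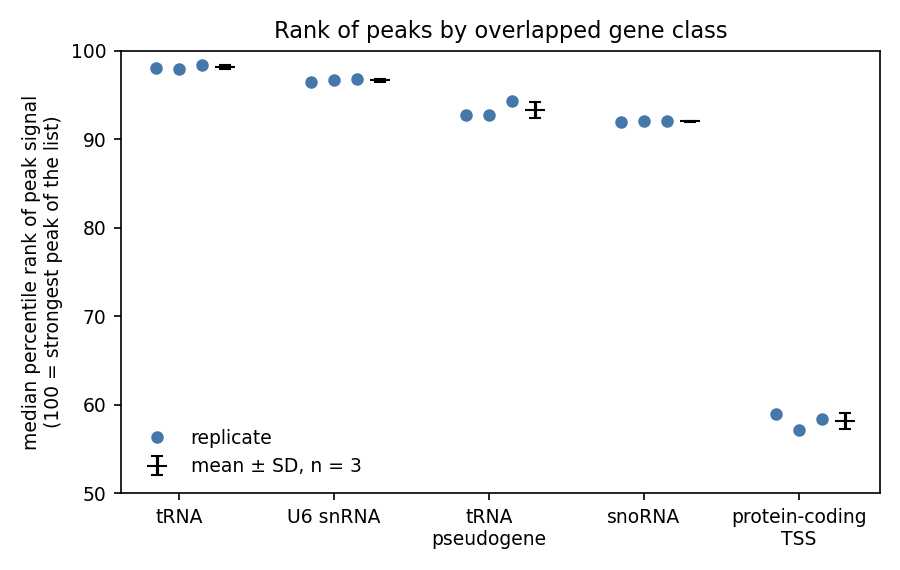
Median percentile rank by signal of the peaks overlapping each gene class, within the list of each replicate (points, 3 replicates, with mean ± SD beside them); the axis starts at 50 and higher means stronger. Peaks over tRNA genes stood at 98.2 ± 0.267 and peaks over protein-coding TSS at 58.1 ± 0.936.

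The replicates were compared with the reproducible list. One of the strongest 1914 peaks of a replicate overlapped 90.2% ± 1.07 of the reproducible peaks (mean ± SD, n = 3), and 1608 reproducible peaks (84.0%) were overlapped in all 3 replicates. Across 1644 intervals covered in every list, Spearman's rho of the signal was 0.974 between replicates 1 and 2, 0.972 between 1 and 3 and 0.977 between 2 and 3. The signal of the reproducible list had rho of 0.959 with the pooled list and 0.955 to 0.964 with the replicates. These values are across intervals, which are not independent replicates.

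The summit position was measured relative to the start of the gene on its own strand. At tRNA genes with no other tRNA gene within 1000 bp, the nearest reproducible summit lay 13 bp downstream of the start (median of 360 genes, quartiles 11 and 16 bp). The median length of these genes was 73 bp. The medians of the replicates' lists averaged 19.3 ± 2.31 bp (SD, n = 3). The spread was wider there, with quartiles of 12 and 56 bp in replicate 1, 13 and 62.5 bp in replicate 2, and 11 and 62 bp in replicate 3. At occupied snoRNA genes the summit lay upstream of the start, at a median of -38 bp (80 genes, quartiles -53 and 3.75 bp), and at 71.2% of these genes it was upstream, against 19.2% of all 583 tRNA genes with a summit within 300 bp and 4.17% of the 360 with no other tRNA gene nearby. In the lists of replicates 1, 2 and 3 the snoRNA median was -29, -30 and -29 bp, and the summit was upstream at 74.7%, 65.8% and 78.5% of the snoRNA genes, 19.8%, 24.1% and 25.3% of all tRNA genes and 10.99%, 14.1% and 16.9% of those with no other tRNA gene nearby. At U6 genes the summit lay at a median of 11 bp (18 genes with a summit within 300 bp). The snoRNA and U6 positions were measured after the data had been seen.

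**Figure D3:**
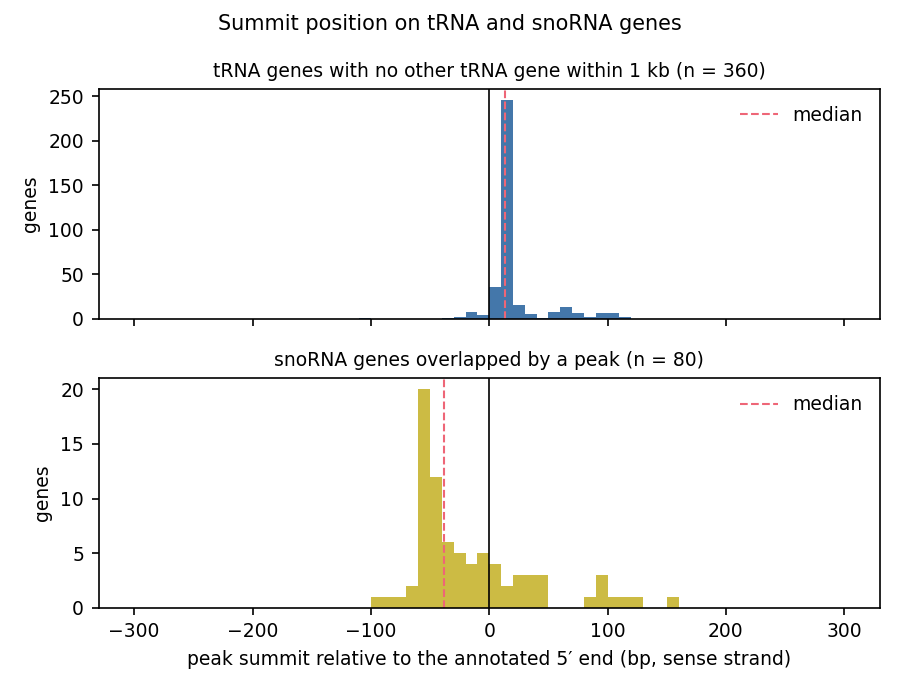
Position of the nearest reproducible peak summit relative to the annotated start of the gene (bp, sense strand, bins of equal width) for 360 tRNA genes with no other tRNA gene nearby and 80 occupied snoRNA genes; the dashed lines are medians. The tRNA median is 13 bp inside the gene and the snoRNA median is at -38 bp, upstream of it.

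Promoters of protein-coding genes were tested in 14 gene lists fixed before the data were examined, after leaving out peaks within 500 bp of a Pol III gene. A summit lay within 500 bp of a TSS of 168 of 19971 genes (0.841%). Of the 78 ribosomal protein genes 4 were among them (rpl-35, rpl-3, rpl-18A and rpl-15, 5.13% against 0.824% of other genes), with signals of 117, 117, 92.7 and 81.4, and the list did not pass (one-sided Fisher exact p = 0.00425, adjusted p = 0.0595 over the 14 lists). None of the 14 lists passed after adjustment, and 1 had an unadjusted p under 0.05. The cuticle collagens had 1 gene with a peak (col-40, signal 871), the heat shock list 1 (hsp-110) and the proteasome list 1 (rpn-3), and the last 2 shared a peak with signal 87.4. The histones, vitellogenins, major sperm proteins, translation factors, Pol III machinery, aminoacyl-tRNA synthetases, P granule genes and the muscle, neuron and intestine markers had 0 genes with a peak. No reproducible peak overlapped rpc-1 itself (IV, 7160135 to 7165748), and the nearest summit lay 82135 bp from its TSS. The promoters with the highest signal were those of wrt-3 (6591), twk-5 (6462), F55A11.6 (5562), Y53G8AL.4 (5488), pdl-1 (5430), Y75B12B.11 (5266), W08A12.2 (5200), C41C4.9 (5166), gst-27 (5119) and gfrl-1 (4446). At 9 of these 10 promoters a small RNA gene lay within 200 bp of the summit, a snoRNA gene at 7 of them, and W08A12.2 was the exception. Of all 180 peaks at protein-coding promoters, 34 had a small RNA gene within that distance. The ribosomal protein list passed in the reproducible peaks found in every replicate (Fisher exact, adjusted p = 0.0198) and without any 1 replicate (adjusted p = 0.0229 to 0.0243). These settings only remove peaks from the reproducible list. The same 4 genes kept a peak in each of them, so they are not separate support. The list also passed in the strongest peaks of the pooled list, where 12 of 78 genes had a peak (Fisher exact, adjusted p = 1.55e-09). With a distance of 250 bp to the TSS in place of 500 bp, 0 of the 78 had one (Fisher exact, adjusted p = 1), as with only the strongest 957 peaks.

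The peak lists of the 2 genome builds were set side by side without converting coordinates. The reproducible list held 2283 peaks on ce10 and 1914 on ce11, a ratio of 1.19, while the pooled lists held 30000 on both and those of replicate 1 held 24186 and 24182. The commonest peak width was 600 bp in the reproducible ce11 list and 456 bp in the reproducible ce10 list and both pooled lists. The X chromosome held 547 reproducible ce11 peaks (28.6%) and 581 reproducible ce10 peaks (25.4%). The mitochondrial genome held 22 of the reproducible ce10 peaks and 0 of the reproducible ce11 peaks.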

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

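No test was chosen after a result was seen in this part, and none was run on the values given here. The mitochondrial genome was outside the comparisons, and 22 of the 2283 reproducible ce10 peaks lay on it, above the 0 found in the reproducible ce11 list. The ce11 lists of replicates 1, 2 and 3 held 23, 24 and 25 mitochondrial peaks, and the pooled ce11 list held 25. The control was not analysed here, so the level these peaks would have without the tagged protein is not known.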

How the results depend on the processing

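The alternatives chosen only after the data were seen were tRNA occupancy from each replicate's own peaks, snoRNA genes with 100 bp upstream, 5S genes with less than 50% repeated sequence, and promoter lists without peaks near snoRNA genes or tRNA pseudogenes. Of 181 alternative values for 27 results, 153 kept their direction and side of the threshold, or stayed within the spread where no test was made. The share of tRNA genes occupied was 90.8% to 96.4% and passed under all alternatives. With the strongest 957 peaks, 5S rRNA genes (6.25%), other spliceosomal RNA genes (1.30%) and spliced leader genes (3.23%) no longer passed, the tRNA difference between X and autosomes (4.28 points) passed, and the B box difference turned to -1.47 points. In the peaks found in every replicate the other spliceosomal RNA genes (2.60%) and spliced leader genes (6.45%) did not pass. Without each replicate in turn they were at 2.60% to 3.90% and at 6.45% throughout. Both passed with the pooled list (9.09% and 16.1%) and with shortened peaks (5.19% and 12.9%). The B box difference was -3.38 points with the pooled list and -0.339 with at most 2 mismatches. With peaks shortened to 100 bp either side of the summit, the X difference was -3.13 and the nested difference 2.38 points. In place of 0 promoter lists, 1 passed with the pooled list, with the peaks found in every replicate, without each replicate in turn (1 each time), and with peaks near snoRNA genes and tRNA pseudogenes left out too. The replicates' share of top peaks at tRNA genes was 70.5%, 77.0%, 59.2% and 34.6% with the top 250, 500, 1000 and 2000 peaks. The tRNA rank was 96.3 in the upper 50% of each list. The replicate overlap was 78.9% when at least 50% of a peak had to be covered and 99.5% with all peaks of each list. The cause was not tested. Depth is unknown, so how it limits the weaker peaks cannot be given.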

Other observations

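The tests of the shoulders and open promoters, of the origin of the ce11 list, of snoRNA genes and of chromosome position were chosen only after the results were seen. A B box within 100 bp, with at most 1 mismatch on the sense strand, was found at 39 of the 84 occupied snoRNA genes (46.4%) and at 5 of the 262 without a peak (1.91%, two-sided Fisher exact p = 1.21e-22). Occupancy did not pass a test for a difference between the 213 snoRNA genes inside protein-coding genes (23.5%) and the 133 outside (25.6%, two-sided Fisher exact p = 0.700). Of the 1018 reproducible peaks away from annotated small RNA genes, the strongest lay inside zip-7 (IV, 16503346 to 16504227, signal 6946) and lips-10 (II, 8441269 to 8442144, signal 6082), and both held a B box near the summit. Another, between genes on X (1837437 to 1838338, signal 5773), held none.

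The peaks away from small RNA genes lay nearer the ends of the chromosomes than those at small RNA genes, except on chromosome IV. In the outer parts of the autosomes (the 66.7% of a chromosome nearest its ends) were 631 of 726 such intervals, with peaks of the same interval counted once (86.9%, exact binomial 95% interval 84.2 to 89.3%), against 350 of 508 at small RNA genes (68.9%, two-sided Fisher exact p = 2.52e-14) while an even spread would give 66.7%. On X the shares were 84.97% and 68.2%, and on chromosome IV, where the order was the opposite, 80.5% and 82.9%. On autosomes the share was 92.3% for those with a B box and 77.0% for those without.

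One pattern is that some Pol III genes had no peak. The 5S genes without one had a median of 94.8% repeated 36-base words (order-statistic 95% interval 85.1 to 100%), against 70.7% in those with one, so reads shared between copies may account for missing peaks, although the difference itself did not pass (permutation p = 0.0991). For the 22 tRNA genes the tables argue against a missing B box at most of them, since 81.8% held one. With at most 2 mismatches all 22 held one, as did 588 of 590 occupied genes, so the search hardly separates tRNA genes. Whether these B boxes work was not tested. The tables also argue against the reproducibility threshold as the whole cause. A peak in the upper 50% of ranks in all 3 replicate lists was found at 13.6%, and 7 had a peak in none. For the 3, 6 and 6 genes with a peak in 1, 2 and 3 lists a weak signal under the threshold stays open. Repeated sequence at these tRNA genes had a median of 24.2%, against 11.4% in occupied genes (permutation p = 0.0001, the smallest it can give). The permutation tests of repeats at 5S and tRNA genes were one-sided and treat each gene as independent. The tRNA p-value may be too small, since T22A3.t2, T22A3.t3 and T22A3.t4 lay together, as did F28H6.t3, F28H6.t4 and F28H6.t6 on X. All of these were over 50%. The interval of the median, 1.79 to 57.8%, crosses the 50% set beforehand because the genes differ. At 10 of the 22 genes the share was 4.81% or less, below the occupied median, and repeats do not account for the missing peak there. At 7 it was over 50%, and repeats cannot be told apart from other causes there. Of the 2 5S genes with less than 50% repeated words 1 had a peak. With a single group, no difference between groups could be set against these.

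A further pattern is the 1018 peaks away from annotated small RNA genes, of which 760 (74.7%) were overlapped by a top peak of every replicate. The tables argue against shoulders of neighbouring peaks as the main source, since 20.4% had a small RNA gene within 1000 bp (12.8% of random positions), and against unannotated copies of tRNA genes, since 9.82% had a tRNA-like match near the summit (3.73% in windows 1000 bp away). A B box on either strand was 6.01 times as frequent within 100 bp of the summit as 1000 bp away (63.8% against 10.6%, permutation p = 0.0001, the smallest it can give), and the ratio was 6.17 ± 0.219 in the replicates' own lists (SD, n = 3). A candidate explanation is binding at B box sites outside annotated genes; whether these sites are transcribed was not tested, and repeated sequence that holds a B box stays open for part of them, since the median share of repeated 36-base words around the summit was 5.28% (16.98% at the other peaks) but 216 of the 1018 were over 50%. Of these peaks 14.3% lay within 500 bp of an annotated protein-coding TSS, against 22.3% of random positions, so most were away from annotated TSS. The random positions were spread evenly along each chromosome, whereas these peaks lay mostly in the outer parts. The lower share therefore cannot decide whether open promoters are a source of part of them.

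Another pattern is that the reproducible ce11 list shared no peak exactly with the pooled and replicate lists. The tables argue against a sample with other binding sites, since 91.5% of its peaks overlapped one of the strongest 1914 pooled peaks. That overlap cannot separate RPC-1 from another protein bound at the same sites. Another call on the same libraries cannot be told apart from another sample bound at these sites. The rank correlation of the list with the pooled list (0.959) was below those between replicates (0.972 to 0.977). However, the commonest widths of 600 and 456 bp differ, and other settings could lower this correlation.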
